A study of Mus musculus with 2 samples.

How the data were processed

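Single-cell RNA libraries of sorted lung immune cells were compared between 1 niche and 1 distal library, both from lungs collected 7 days after injection of labelling 4T1 cells. Groups came from the sample titles. The number of animals behind each library and the sort gates are not given in the sources used here. The deposited matrices hold UMI counts per gene and barcode, not normalized, made with Cell Ranger per the file headers. The header of the distal matrix names software version 3.0.2 and that of the niche matrix cellranger-6.0.0, whereas the submitters' processing notes list Cell Ranger 3.02, Seurat 4.1.1, RSEM and Bowtie2, with mm10 and GRCm38 as genome builds, without saying which step used which. Counting with different software versions and different gene annotations is confounded with the group, since each group is 1 library.

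The gene lists of the deposited counts differed: 30149 gene rows in the distal and 32285 in the niche matrix, of which 29413 had the same Ensembl identifier and 27462 of these the same symbol. Only shared identifiers entered comparisons. Coordinates and exon overlaps were taken from the GENCODE annotation of GRCm38 in the reference, in which all 29413 shared identifiers were found. Of these, 442 share exonic bases on the same strand with a gene held by 1 list only, and a read in such a place can be counted in 1 library and discarded as ambiguous in the other.

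Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. This removed 405 distal and 161 niche barcodes with many mitochondrial UMIs, among them all 9 and 5 with few genes, and left 3540 and 3081 cells with medians of 5794.5 and 11197 UMIs. Scrublet, as built into scanpy 1.11.5, was run per library with an expected doublet rate of 0.03. It called 4 distal and 1 niche doublets, 0.0755% of 6621 cells, so it was taken as not having worked. The 5 calls were removed, clusters with markers of more than 1 lineage were left unnamed as mixed, and an alternative left out the highest 5% of scores. Both libraries were clustered together without alignment, on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

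Markers of each cell type were fixed before the data were examined, but the scoring was not. The thresholds below were set after the clusters had been seen, and this scoring followed 2 other attempts, one based on folds and one on the fraction of markers present. A marker counted as present in a cluster when its level reached 0.15 of that in the highest cluster and a share of 0.1 of the cells had a UMI. A name needed 0.75 of its markers and at least 3. Clusters that reached only 0.4 of the interstitial macrophage markers or 0.5 of the classical monocyte markers were called monocyte/macrophage-like. Such a cluster that also reached 0.25 of T or B cell markers was called mixed, as were clusters named for more than 1 lineage and lymphocyte clusters with 0.5 of the interstitial macrophage markers. Clusters whose 10 leading genes held more markers of another class than of their own were kept apart, and clusters with a median UMI count more than 3 times below that of their library and no marker among the leading genes were left unnamed. The shares of all clusters kept out of classes in this way are given with the results.

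UMIs were summed over the cells of a class and expressed as CPM of all UMIs of the class. The log2 ratio of niche over distal CPM had 0.5 UMI added to each sum, with an exact conditional binomial interval, and shares of cells had exact Clopper-Pearson intervals, all at 95%. Ratios of shares had conditional intervals of the same kind. Classes needed at least 50 cells in each library. No p-value was computed, since cells are not replicates. For each gene list fixed before the data were examined, the median log2 ratio of members with at least 20 UMIs was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with fewer than 5 measured members in a class were not reported. The ratio step was tested on counts simulated from the means of the monocyte/macrophage-like class with some genes altered. Of the naming rule described below, only the minimum of 100 UMIs and the interval beyond 1.5-fold were tested. Among altered genes that still had at least 100 UMIs, all 50 at a fold of 4 and all 35 at a fold of 0.25 passed. Only 70% of 50 genes at a fold of 2 and 56.8% of 44 at a fold of 0.5 did. Altered genes that fell below the minimum of UMIs are not in these shares. Of 8794 unaltered genes 0 passed, and 95.4% of their intervals held the true value, over 8973 genes in all.

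Named genes followed a rule fixed before the data were examined. Genes had at least 100 UMIs in the class and 50 CPM in the higher library. Mitochondrial, ribosomal protein, haemoglobin, receptor segment and unnamed genes were left out, as were genes below 5% of their level in another class. Those whose interval lay wholly beyond 1.5-fold were ranked by ratio, and the first 10 in each direction were named in the larger classes and the first 4 in the others. In addition, up to 4 members of each list with the largest ratios could be named. Since most genes named by the rule were linked to the annotations, the rule was applied again without genes that overlap a gene of 1 list or shift alike in unrelated classes (a median log2 ratio of at least 1 there, with the same sign and at least 0.5 of the gene's own ratio). The median in unrelated classes used only those classes with at least 20 UMIs of the gene, so it can rest on few of them. This second naming was chosen after the data were seen. Whole-library genes and a few list members were also named after their values were seen.

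The alternatives chosen before the data were examined were other filters on cells (at least 500 genes, a lower mitochondrial limit, none), doublets kept, Leiden resolutions of 0.5 and 2, genes centred within each library, and cells thinned to 1000 UMIs. They also included ratios centred on the median gene, CPM without the 50 most abundant genes, means of per-cell CPM, and other UMI minimums. Alternatives added after seeing the data were other naming thresholds, other totals for shares, the highest Scrublet scores left out, the largest cluster of a class alone, annotation-linked genes left out, and droplets counted by at least 3 genes of a cell type without clusters. UMI counts in gene rows of 1 list only were left out of comparisons and are described in the closing section. Reporter rows existed in the distal list alone and held 0 UMIs for mCHERRY, 1 for eGFP and 2 for tdtomato, none above the 3 UMIs that a count of 0 allows. The niche list had no such rows, so reporter RNA could not be compared.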

Results

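Single-cell RNA was measured in immune cells sorted from the lungs of female Balb/c mice, collected 7 days after intravenous injection of labelling 4T1 cells. 4T1 is a mouse mammary carcinoma line that seeds the lung, and in the labelling system known from this line the cancer cells release a fluorescent protein that can enter neighbouring cells, so that cells close to metastases can be sorted apart from cells of the rest of the lung. There was 1 library of niche immune cells and 1 library of distal lung immune cells, both made with a droplet-based 3′ kit. The distal library held 3945 barcodes and 22323465 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), with a median of 5272 UMIs and 1933 genes per barcode. The niche library held 3242 barcodes and 38036915 UMIs, with a median of 10740.5 UMIs and 2835.5 genes. After filtering and removal of the few called doublets, 3536 distal and 3080 niche cells were compared. With 1 library per group there was no replicate and no test, so every difference is one between these 2 libraries, and all intervals are 95% intervals that cover counting error only.

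The first comparison asked which immune cells made up each library. Monocyte/macrophage-like cells, which carried markers of interstitial macrophages or classical monocytes without meeting the full set of either, made up 62.0% of niche cells (1911 cells, Clopper-Pearson interval 60.3 to 63.8) and 9.11% of distal cells (322 cells, 8.18 to 10.1), a ratio of 6.81 (6.05 to 7.69). Alveolar macrophage-like cells, the resident phagocytes of the air spaces, showed the opposite, with 32.0% of distal cells (1131 cells, 30.4 to 33.6) and 0.260% of niche cells (8 cells, 0.112 to 0.511). Neutrophil-like cells were 10.4% of the distal library and 1.01% of the niche library, a ratio of 0.0964 (0.0646 to 0.139). Lymphocytes were also a lower share of the niche library, at 1.20% against 10.4% for T cell-like cells and 1.23% against 5.71% for B cell-like cells. The corresponding ratios were 0.115 (0.0798 to 0.162) and 0.216 (0.149 to 0.307). These classes held only part of the droplets with lymphocyte RNA. A count of all droplets with at least 3 T cell genes, chosen after the data were seen, gave 6.53% of niche and 12.8% of distal droplets, a ratio of 0.511 (0.430 to 0.604), and the same count gave 0.608 (0.499 to 0.739) for B cell and 0.304 (0.249 to 0.369) for neutrophil genes. Of those niche droplets 17.9%, 23.8% and 21.4% lay in the class of that name, against 76.1%, 64.9% and 71.3% of the distal ones, so the direction held but the size of these differences depended on how the cells were counted. This count used all UMIs of a droplet, and kept niche cells were deeper (median 11197 against 5794.5 UMIs). Most of these niche droplets also held macrophage RNA, 76.6% for T cell, 67.5% for B cell and 61.1% for neutrophil genes. How far depth and mixed droplets set these ratios was not tested.

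Blood monocyte types were a lower share of the niche library as well. Classical monocyte-like cells were 1.56% of niche and 4.58% of distal cells, and non-classical monocyte-like cells, which patrol the vessel wall, were 0.390% and 4.72%. The macrophage and monocyte compartment as a whole was 66.6% of the niche library and 54.0% of the distal library, a ratio of 1.23 (1.16 to 1.31). Dendritic cells, which carry antigen to T cells, were 3.64% and 5.94%, a ratio of 0.612 (0.482 to 0.774). Within them, conventional dendritic-like cells were 1.30% against 3.65%, plasmacytoid dendritic-like cells 0.519% against 0.905%, and migratory dendritic-like cells 1.82% against 1.39%. NK cell-like cells were 0.292% against 1.05%. Interstitial macrophage-like cells were 2.37% against 3.62%, a direction that turned with finer clustering, where the ratio of shares went from 0.655 to 1.39.

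Proliferating monocyte/macrophage-like cells, a cluster led by mitotic genes such as Top2a and Birc5, were 8.02% of niche cells and 1.89% of distal cells. Proliferating alveolar macrophage-like cells were 0.0325% and 2.57%. Several groups of cells stayed outside these classes: mixed clusters were 4.29% of niche and 3.05% of distal cells, a low-UMI cluster 10.3% and 0.594%, and cluster 18 2.31% and 0.679%. The direction for mixed clusters turned in 7 alternatives, with ratios of 0.0720 to 0.787 in place of 1.40. Cluster 18 had macrophage markers but was kept apart because its leading genes held the lymphoid marker Il7r and no marker of its own class. Stromal-like cells were 1.04% and 2.88% despite the sort for immune cells, and alveolar epithelial-like and platelet-like cells were each under 1% of either library. The sort gates were not given in the sources used here and can set all of these shares, as can differences between cell types in uptake of the label, which were not measured. The median UMI count of neutrophil-like cells, 1078 distal and 1236 niche, lay far below that of monocyte/macrophage-like cells, 7530.5 and 12006, so a minimum on UMIs bears on these classes unequally. A class found mostly in 1 library, as alveolar macrophage-like cells were, is also a property of that library.

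**Figure D1:**
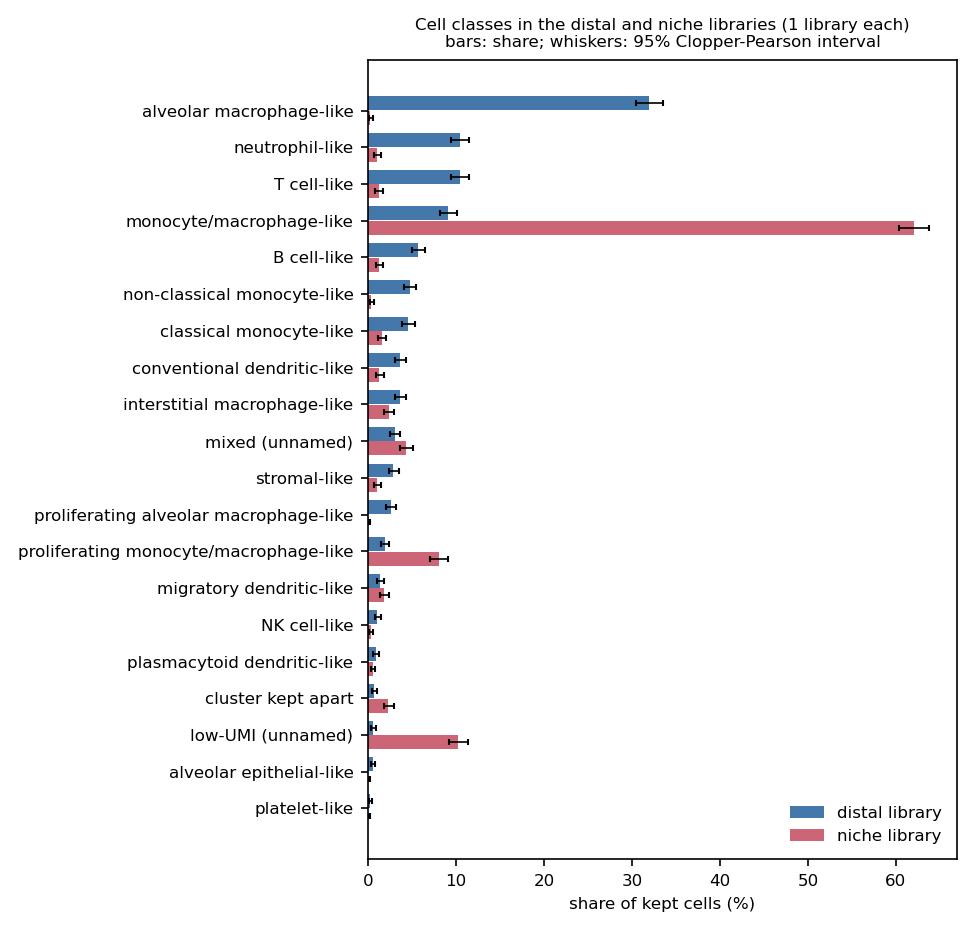
Share of kept cells (%, x axis) in each cell class (y axis) for the distal library (blue, 3536 cells) and the niche library (red, 3080 cells), with whiskers for the 95% Clopper-Pearson interval. Alveolar macrophage-like cells reached 32.0% in the distal library and monocyte/macrophage-like cells 62.0% in the niche library.

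The second comparison asked how the monocyte/macrophage-like cells of the niche library differed from those of the distal library, over 25392727 niche and 2735495 distal UMIs. Interferon gamma response genes were higher in the niche library as a group, and type I interferon response genes were lower. Of 22 measured interferon gamma genes, 21 had a ratio above 0 on the log2 scale, with a median of 0.24 at percentile 99.9 of 10000 random lists matched on expression. Cxcl9, a chemokine that draws activated T cells (chromosome 5, 92321347 to 92328079, GRCm38), was at 5200 CPM (UMIs scaled to the same total in each library) in the niche library and 2937 CPM in the distal library, a log2 ratio of 0.82 (0.79 to 0.86). Ciita, the master activator of MHC class II genes (chromosome 16, 10480059 to 10528418), was at 119 against 53.4 CPM, a log2 ratio of 1.16 (0.92 to 1.41). The interferon-induced GTPase Iigp1 was at 446 against 260 CPM, and Gbp6, which overlaps a gene held by only 1 of the 2 gene lists and is therefore uncertain, at 51.0 against 4.39 CPM. The shift was not confined to this class. The median log2 ratio over T, B, neutrophil, stromal and dendritic classes was 0.91 for Ciita and 0.82 for Iigp1. These medians were close to the genes' own 1.16 and 0.78. Cxcl9 was also higher in niche T cell-like (559 against 4.53 CPM), B cell-like (200 against 10.4 CPM) and stromal-like cells (3447 against 472 CPM). Cxcl9 did not stay once genes linked to the annotations were left out, although its ratio exceeded that of Lap3, which stayed. The ratio of Cxcl9 is therefore uncertain.

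Of 23 type I interferon genes, 22 were lower in the niche library, with a median log2 ratio of -0.50 at percentile 0. Rsad2, an antiviral enzyme (chromosome 12, 26442746 to 26456452), was at 118 CPM in the niche library and 246 CPM in the distal library, a log2 ratio of -1.07 (-1.19 to -0.94). The RNA sensor Ddx58 was at 21.7 against 51.2 CPM, Cmpk2 at 12.6 against 26.7 CPM and Ifit2 at 64.9 against 121 CPM. Cluster 10, led by type I interferon genes, held 13.7% of the distal and 8.27% of the niche cells of this class. A view of the largest cluster alone was chosen after the data were seen. In that cluster, cluster 0, which held 66.8% and 64.4% of the cells, the median of the list was -0.15 and the log2 ratio of Rsad2 was 0.28, while the median of the interferon gamma list was 0.46.

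Genes of hypoxia and glycolysis were higher in the niche library, with 20 of 22 members above 0 and a median log2 ratio of 0.38 at percentile 100. Among them were the cytokine Mif at 526 against 344 CPM and the glycolytic enzyme Pgam1 at 398 against 279 CPM. Hif1a, the hypoxia-responsive transcription factor, was at 232 against 160 CPM, but it overlaps a gene of 1 list only. Oxidative phosphorylation genes had a median of 0.23 (percentile 99.9, 23 of 24 above 0), with the ATP synthase gene Atp5g1 at 437 against 310 CPM. The unfolded protein response list had a median of 0.38 (percentile 100, 11 of 17 above 0), with Creld2 at 97.3 against 59.2 CPM, Pdia4, a protein folding enzyme, at 102 against 62.9 CPM, and Sdf2l1 at 303 against 202 CPM. All 23 cell cycle genes lay above 0, with a median of 0.47 (percentile 100). The replication clamp Pcna was at 114 against 34.4 CPM, and the cyclin Ccna2 at 3.74 against 0.731 CPM. Cluster 7, led by replication genes such as Mcm6, held 12.3% of the niche and 6.83% of the distal cells of this class. It carried 0.47 of the conventional dendritic and 0.45 of the interstitial macrophage markers, so its name is uncertain. In cluster 0 alone the median of the cell cycle list was 0.21.

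Inflammatory and stress genes were lower in the niche library. The NF-kB inflammatory list had a median log2 ratio of -0.28 (percentile 0, 17 of 23 below 0), with the chemokine Cxcl2 at 427 against 600 CPM and the lipopolysaccharide co-receptor Cd14 at 454 against 633 CPM. In cluster 0 alone this median was -0.13. The dissociation stress list, genes that tissue digestion itself can induce, had a median of -0.39 (percentile 0, 17 of 22 below 0), with the phosphatase Dusp1 at 323 against 556 CPM, Egr1 at 71.8 against 123 CPM and Jun at 143 against 222 CPM. Chemokines went both ways around a median of -0.28 (percentile 0.03), whose counting interval of -0.33 to 0.01 held 0. Ccl6 was at 212 against 573 CPM and Ccl9 at 51.4 against 139 CPM, while the monocyte attractant Ccl8 was at 735 against 360 CPM. Ccl8 did not stay once genes linked to the annotations were left out, although its ratio exceeded that of Serpina3g, which stayed. The ratio of Ccl8 is therefore uncertain. The neutrophil granule list had a median of -1.57 (percentile 0, all 15 members below 0), with Prtn3 at 1.10 against 17.2 CPM, and -0.71 in cluster 0 alone. RNA of neutrophils was also counted in other classes: S100a8 was at 11.1 CPM in niche and 252 CPM in distal B cell-like cells, and at 0 and 6.23 CPM in T cell-like cells. The niche values come from 38 and 37 cells with medians of 1736.5 and 2627 UMIs. They lie near the floor and cannot show how neutrophil RNA differed between classes. The naive lymphocyte list (-0.37, and -1.17 to -0.08 across alternatives) and the B cell activation list (-0.20) lay at the lower edge of the random lists, with Klf2 at 72.8 against 212 CPM.

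The remaining lists lay within the middle 95% of random lists. Their median log2 ratios were -0.09 for MHC class II presentation, 0.05 for MHC class I presentation, -0.01 for lipid-associated macrophage genes, -0.03 for cholesterol synthesis, 0.07 for the lysosome and 0.00 for phagocytosis receptors. They were -0.05 for complement, -0.08 for immune regulation, -0.01 for tissue remodelling, 0.14 for growth and Wnt ligands, 0.04 for oxidative stress and -0.19 for T cell activation. The cytotoxic list was at 0.08, the carcinoma and epithelial list at -0.12 and the stromal list at -0.05. Single members of these lists still differed. Apoe, the lipid carrier (chromosome 7, 19696109 to 19699188), was at 2733 against 6646 CPM, a log2 ratio of -1.28 (-1.31 to -1.26), and the class II genes H2-Aa and H2-Eb1 at 7403 against 9373 CPM and 7161 against 8781 CPM. Complement factor B, Cfb (chromosome 17, 34856374 to 34862518), was at 649 against 58.5 CPM, but it overlaps Gm20547, a gene of 1 list only, and its ratio is uncertain. Of the keratins Krt8 and Krt18, genes of epithelial and carcinoma cells, only Krt18 was higher in the niche library beyond counting error, and both were at low levels, Krt8 at 4.21 against 2.19 CPM (107 and 6 UMIs, log2 ratio 0.83, -0.23 to 2.42) and Krt18 at 3.07 against 0.731 CPM (78 and 2 UMIs, 1.76, 0.17 to 5.14).

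**Figure D2:**
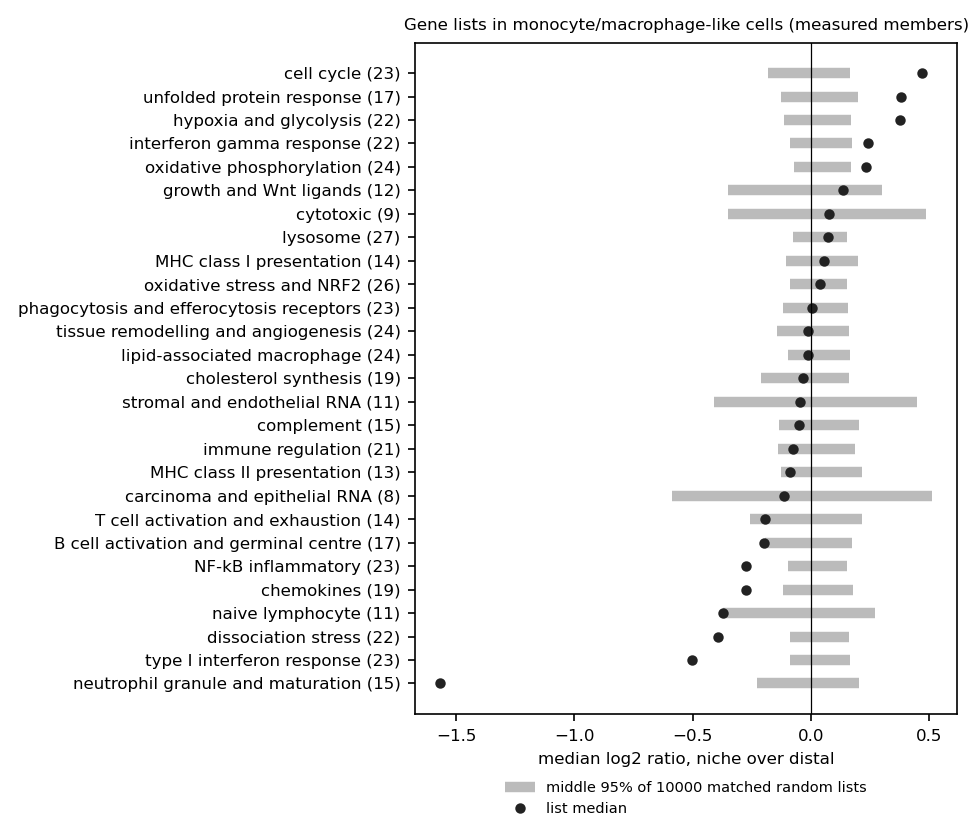
Median log2 ratio of niche over distal CPM (x axis) for each gene list (y axis, number of measured genes in brackets) in monocyte/macrophage-like cells, with grey bars for the middle 95% of 10000 random lists matched on expression. Cell cycle (0.47) lay highest and neutrophil granule genes (-1.57) lowest.

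The genes with the largest ratios in this class did not describe these programmes. By the rule fixed for naming genes, the 10 highest in the niche library were Rnasek, Atp6v0c, Fdx1l, Tnfsf13, Timm23, Fam89b, Apoc2, Nme2, Gng10 and Mrpl53, with log2 ratios from 6.55 to 9.20. Fdx1l and Tnfsf13 had no UMI in the distal cells, so their ratios depend on the 0.5 UMI added to each sum. Of these genes 7 overlap a gene held by only 1 of the 2 lists, and all 10 had a shift of the same sign in unrelated classes, such as T cells and stromal cells. Atp6v0c, a proton pump subunit of all cells (chromosome 17, 24163866 to 24169702), was at 1794 CPM in the niche library and 4.02 CPM in the distal library. The 10 lowest were Ctsk, Ptp4a1, Tonsl, Mmp9, Prg4, Coro1b, Retnla, Slpi, Lyz1 and Ltc4s, with log2 ratios from -7.11 to -3.64, and 6 of them (Ctsk, Ptp4a1, Tonsl, Coro1b, Retnla and Lyz1) met either criterion, against 7.13% of all 9005 genes with enough UMIs. Overlap alone held for 2.35% of those 9005 genes. Genes that met either criterion are called annotation-linked below, although a shift in unrelated classes can also come from RNA of other cells in the droplets.

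Leaving out every gene that met either criterion, a step chosen after the data were seen, brought other genes to the top. Because the second criterion needs a log2 ratio of at least 1 in unrelated classes, genes with small ratios of their own rarely meet it, and some of those that follow shifted alike there: Srsf7 by 0.77 (own ratio 0.83), Spp1 by 0.58 and Serpina3g by 0.51, but Lap3 by 0.18 and Fabp5 by 0.13. The secreted matrix protein Spp1 (chromosome 5, 104435118 to 104441050) was at 328 CPM in the niche library and 161 CPM in the distal library, a log2 ratio of 1.03 (0.89 to 1.17). The fatty acid binding protein Fabp5 was at 391 against 218 CPM, the protease inhibitor Serpina3g at 648 against 342 CPM, and the aminopeptidase Lap3 at 253 against 145 CPM. Lower in the niche library, over all clusters of the class, were the gelatinase Mmp9 at 1.22 against 60.0 CPM, the lubricant protein Prg4 at 3.98 against 111 CPM, the protease inhibitor Slpi at 20.7 against 306 CPM, the acute phase gene Saa3 at 78.2 against 667 CPM and complement C4b at 13.2 against 92.9 CPM. Cluster 26, which is led by Saa3, Prg4 and C4b among others, held 4.66% of the distal cells (15 cells) and 0.314% of the niche cells (6 cells) of the class. In cluster 0 alone the log2 ratio of Saa3 was 1.18, that of Slpi -0.02 and that of C4b -0.42, while Spp1 was at 0.74. Mmp9 and Prg4 were almost absent from cluster 0, where Mmp9 had 13 niche and 0 distal UMIs, too few for a ratio, and Prg4 had none in either library.

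**Figure D3:**
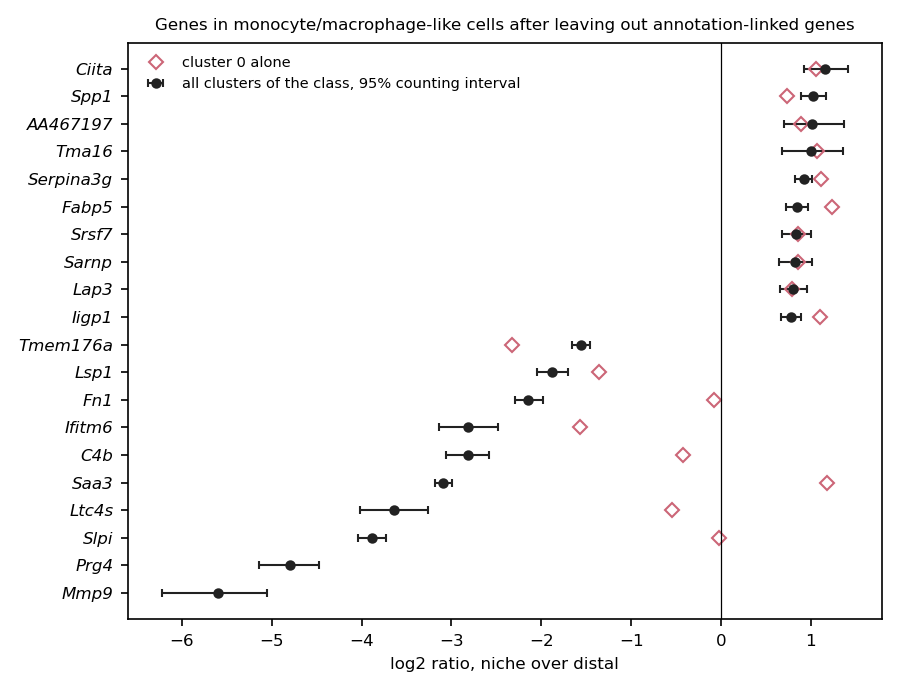
Log2 ratio of niche over distal CPM (x axis) for the genes with the largest ratios (y axis) in monocyte/macrophage-like cells after annotation-linked genes were left out, with 95% counting intervals (black) and the ratio in cluster 0 alone (red diamonds, where at least 20 UMIs were counted). Genes higher in the niche library kept their side in cluster 0 (Ciita 1.06), whereas Saa3 went from -3.09 to 1.18.

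The same question was asked of dendritic cells, over 112 niche and 210 distal cells. Interferon gamma response genes were higher in the niche library (median log2 ratio 0.42, percentile 100, 17 of 20 above 0), with the guanylate binding protein Gbp4 at 230 against 99.6 CPM, Cxcl9 at 1757 against 768 CPM and Cxcl10 at 314 against 139 CPM. The chemokine list had a median of 0.90 (percentile 100, 14 of 19 above 0), with Ccl7, an attractant of monocytes, at 137 against 10.3 CPM, Ccl8 at 295 against 31.5 CPM and Ccl12 at 148 against 17.2 CPM, while Ccl6 was lower at 194 against 584 CPM. The complement list (0.74, percentile 100, 7 of 12 above 0) included C1qb at 793 against 192 CPM and C1qc at 532 against 139 CPM, both genes of macrophages. Naive lymphocyte genes had a median of 0.40 (percentile 98.3), through Ccr7, the lymph node homing receptor, at 1347 against 664 CPM and Il7r at 199 against 76.1 CPM. The tissue remodelling list (0.33, percentile 99.8) held the macrophage elastase Mmp12 at 354 against 96.7 CPM, and oxidative stress genes were at 0.21 (percentile 99.7).

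Lower in niche dendritic cells were the dissociation stress list (-0.58, percentile 0, 19 of 22 below 0), with Fos at 581 against 1180 CPM, the neutrophil granule list (-1.80, percentile 0, 9 of 10 below 0), with S100a8 at 44.3 against 372 CPM, and the cell cycle list (-0.44, percentile 0.17, 12 of 18 below 0). All other lists measured there lay within the middle 95% of random lists. After annotation-linked genes were left out, the largest ratios higher in the niche library included Mmp25, a membrane-bound protease, at 140 against 10.3 CPM and Pdcd1lg2, a ligand of the checkpoint receptor PD-1, at 123 against 27.5 CPM. Mmp25 only narrowly missed the second criterion, with a log2 ratio of 1.77 in unrelated classes against its own 3.73. Lower was Anxa1, a regulator of inflammation, at 87.6 against 280 CPM. Retnla, at 0 UMIs against 296 UMIs, passed the criteria only because a count of 0 inflates its ratio, as its log2 ratio in unrelated classes was -4.11. The niche part of this compartment was 50% migratory and 35.7% conventional dendritic-like cells, and the distal part 23.3% and 61.4%. RNA of macrophages in other classes also differed, from a source that was not tested for these classes: in T cell-like cells Cxcl9 was at 559 CPM in the niche library and 4.53 CPM in the distal library, and C1qb at 62.1 and 4.53 CPM. Of the genes named by the fixed rule, 8 of 10 higher (Rnasek, Atp6v0c, Nme2, Gng10, Cfb, Timm23, Ube2v1 and Tomm6) and 9 of 10 lower (Tonsl, Ptp4a1, Coro1b, Chil3, Lyz1, Taf6l, Wdr89, Rnf149 and Lpl) were annotation-linked. The naive lymphocyte median (0.40), whose counting interval of -0.34 to 1.06 held 0, was -0.62 with means of per-cell CPM and -0.32 with a minimum of 100 UMIs. The tissue remodelling median turned to -0.34 when cells were thinned to 1000 UMIs, and the cell cycle median to 0.12 with a higher minimum of UMIs.

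Interstitial macrophage-like cells were compared over 73 niche and 128 distal cells. Chemokine genes were higher in the niche library (median log2 ratio 0.52, 11 of 17 above 0), with Cxcl10 at 1125 against 300 CPM, Ccl7 at 1442 against 463 CPM and Ccl2, the main attractant of classical monocytes, at 1240 against 581 CPM. Hypoxia and glycolysis genes had a median of 0.45 (15 of 17 above 0), with the hexokinase Hk2 at 121 against 62.7 CPM. Oxidative phosphorylation genes were at 0.32 (23 of 24 above 0), the unfolded protein response list at 0.53 (12 of 15 above 0), the cell cycle list at 0.43 (13 of 15 above 0) with Pcna at 110 against 33.3 CPM, and tissue remodelling at 0.34. All of these lay beyond the middle 95% of random lists. Fabp5 was at 262 against 15.4 CPM, a log2 ratio of 4.04, the scavenger receptor Cd163 at 102 against 43.5 CPM and the haem-degrading enzyme Hmox1 at 339 against 152 CPM.

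MHC class II genes were lower in niche interstitial macrophage-like cells (median log2 ratio -0.46, 9 of 11 below 0), with H2-Eb1 at 6863 against 10798 CPM, although their activator Ciita was at 79.5 against 29.4 CPM. The neutrophil granule list (-0.93), the naive lymphocyte list (-0.45) and the dissociation stress list (-0.26) lay below the random range as well, and the calcium-binding protein S100a6 was at 87.4 against 520 CPM. Lists not named here lay within the middle 95% of random lists in this class. Of the genes named by the fixed rule, all 4 higher (Rnasek, Atp6v0c, Nme2 and Gng10) and 3 of 4 lower (Coro1b, Wdr89 and Rnf149, but not S100a6) were annotation-linked. The chemokine median turned to -0.09 without annotation-linked genes. Cxcl10, Ccl7 and Pcna were not among the largest ratios left once those genes were left out. Their ratios exceeded that of Cd163, which stayed, so they are uncertain. Here and in the groups below, that step drops members partly for a shift of the same sign in unrelated classes. Part of such a turn can therefore come from the choice of members. The tissue remodelling and dissociation stress medians turned to -0.12 and 0.20 with finer clustering. Finer clustering also brought the log2 ratio of Cxcl10 from 1.91 to 0.27, that of Ciita from 1.41 to 0.22 and that of Hk2 from 0.94 to 0.01, so these differences depend on how the class is drawn.

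In the proliferating monocyte/macrophage-like cluster, with 247 niche and 67 distal cells, interferon gamma genes were again higher in the niche library (median log2 ratio 0.63, 18 of 21 above 0), with Gbp2 at 257 against 107 CPM and Gbp4 at 254 against 103 CPM. Lysosome (0.43, 22 of 27 above 0), lipid-associated macrophage (0.42), phagocytosis receptor (0.40), cholesterol synthesis (0.46), complement (0.46), oxidative stress (0.43), hypoxia (0.32), tissue remodelling (0.29), unfolded protein response (0.26), immune regulation (0.25), chemokine (0.46) and neutrophil granule (0.48) genes lay above the random range. Below it lay cell cycle (-0.58), dissociation stress (-0.70), MHC class II (-0.27), T cell activation (-0.46), naive lymphocyte (-0.48) and B cell activation (-0.48) genes. This cluster carried a larger part of the conventional dendritic markers than of the interstitial macrophage or classical monocyte markers, so its name is uncertain and its lists can reflect different mixtures of both kinds in each library. RNA of other cell types was higher in its distal cells, with the plasma cell gene Jchain at 0.529 CPM in the niche and 125 CPM in the distal library and the dendritic cell genes Xcr1 at 21.7 and 109 CPM and Napsa at 51.7 and 276 CPM. Ch25h, a cholesterol hydroxylase, was at 164 against 43.8 CPM, a log2 ratio of 1.89 that was 0.99 in unrelated classes and 0.50 with cells thinned to 1000 UMIs. By the fixed rule all 4 genes named higher (Atp6v0c, Rnasek, Nme2 and Fam89b) were annotation-linked, and of the 4 named lower (Jchain, Tonsl, Cd24a and Cxcl13) only Tonsl was. All other lists lay within the middle 95% of random lists. The chemokine median turned to -0.54 without annotation-linked genes, and the neutrophil granule median to -0.24 with no minimum of UMIs.

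Over all kept cells, levels followed the makeup of each library. Ear2, a ribonuclease of alveolar macrophages, was at 17.8 CPM in the niche library and 908 CPM in the distal library, S100a8 of neutrophils at 221 against 1851 CPM, Cd3e of T cells at 10.2 against 51.9 CPM and Cd79a of B cells at 28.5 against 95.2 CPM. C1qa was at 3932 against 975 CPM and Cxcl9 at 4440 against 653 CPM. Sftpc, the surfactant gene of alveolar epithelium, was at 74.0 against 1433 CPM. The list medians beyond the random range were 0.99 for MHC class II, 0.91 for interferon gamma, 0.57 for hypoxia and glycolysis, 0.44 for type I interferon, 0.37 for chemokine, 0.34 for oxidative phosphorylation and 0.26 for unfolded protein response genes. Below it lay the carcinoma and epithelial (-3.76), neutrophil granule (-3.05), T cell activation (-2.49), cytotoxic (-2.36), naive lymphocyte (-1.39), stromal (-1.36), B cell activation (-0.50), lipid-associated (-0.40) and oxidative stress (-0.25) lists. Within the carcinoma and epithelial list, Krt8 (4.06 against 2.08 CPM) was nevertheless higher in the niche library.

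The macrophage and monocyte compartment, whose distal part was 52.9% cells of the main alveolar macrophage-like cluster and whose niche part was 60.0% cells of cluster 0, differed from the whole library in the sign of several lists. The stromal, cytotoxic, naive lymphocyte and T cell activation lists lay beyond the random range in both, with opposite signs. Other lists differed in sign as well, such as cell cycle, which was at -0.12 and within the random range over the whole library. Alveolar macrophage genes were lowest in the niche part of the compartment, with Fabp1 at 0.823 against 382 CPM, Plet1 at 2.73 against 679 CPM and Siglecf, a sialic acid receptor, at 0.486 against 72.2 CPM. Lists above the random range were stromal (1.41), MHC class II (1.17), interferon gamma (1.11), cytotoxic (0.96), cell cycle (0.93), hypoxia and glycolysis (0.72), naive lymphocyte (0.70), chemokine (0.66), T cell activation (0.59), MHC class I (0.51) and type I interferon (0.43) genes. Neutrophil granule (-1.58), lipid-associated (-0.67), phagocytosis receptor (-0.40) and oxidative stress (-0.33) genes lay below it. The compartment leaves out the proliferating clusters, which were set apart by cell cycle genes, so its cell cycle median describes the remaining cells only. These medians compare different mixtures of cells, and some turned: cell cycle to -0.49 with doublets kept and chemokine to -0.13 without annotation-linked genes. The naive lymphocyte median, whose counting interval of -0.04 to 0.88 held 0, was -0.31 without them. In this compartment too, all 10 genes named higher by the fixed rule (Rnasek, Apoc2, Atp6v0c, Fdx1l, Mrpl53, Gng10, Nme2, Timm23, Rab4b and Fam89b) were annotation-linked. Of the 10 named lower, Cidec, Atp6v0d2 and Ptp4a1 were, and Perp, Fabp1, Krt79, Slc6a4, Plet1, Kcnn3 and Siglecf were not. Lists not named for either comparison lay within the middle 95% of random lists.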

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

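The test of the annotations below was chosen after the result was seen.

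UMIs were found in gene rows that no comparison could use, because only 1 of the 2 lists held them. The distal library had 40364 such UMIs (0.181% of its total) in 736 rows, among them Gm9843 and Pnp under an identifier of its own. The niche library had 217629 such UMIs (0.572%) in 2872 rows, with Ifi30, a lysosomal thiol reductase of antigen presenting cells, at 66391 UMIs. The 2 libraries include no control against which to set these counts, which are above the 3 UMIs that a count of 0 allows.

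The genes with the largest ratios in monocyte/macrophage-like cells, from Rnasek to Mrpl53, were higher in the niche library by log2 ratios of 6.55 to 9.20. All 10 of 10 either overlap a gene of 1 list only or shift alike in unrelated classes, against 7.13% of 9005 genes. The second criterion needs a log2 ratio of at least 1 elsewhere, so genes picked for large ratios meet it more readily than most. Overlap alone held for 7 of 10, against 2.35% of the 9005 genes. Counting with 2 annotations is therefore a candidate explanation for all 10 genes. A biological difference between niche and distal tissue that acts on T, B, stromal and myeloid cells alike was not tested and stays open. For genes such as Cfb (log2 ratio 3.47), where an overlap exists beside a known response to interferon, both remain open.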

How the results depend on the processing

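Alternatives chosen only after the result was seen are named as added. Values below are ratios of shares or log2 ratios of niche over distal. The 7 main share ratios kept their value within counting error in 80 alternatives, moved in 13 and turned in 0. The main list medians of monocyte/macrophage-like cells kept theirs in 118, moved in 26 and also turned in 0. Gene ratios stayed within error 1951 times, moved with the same sign 276 times and turned 7 times. The ratio for alveolar macrophage-like cells ranged from 0.00576 to 0.0105 and that for monocyte/macrophage-like cells from 5.85 to 7.65. No paired analysis was possible because each group has 1 library. The cause was not tested for any of the shifts that follow.

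The macrophage and monocyte share ratio (1.23) was 1.45 with no filter on cells, 1.37 with doublets kept and 1.08 at Leiden resolution 0.5. The monocyte/macrophage-like ratio (6.81) was 5.97 at that resolution and 5.85 with genes centred within library, where the B cell ratio was 0 (from 0.216). The neutrophil ratio was 0.148 with at least 500 genes. The interstitial macrophage-like ratio (0.655) turned to 1.39 at resolution 2 and 1.21 with cells thinned before clustering. The ratio of mixed clusters (1.40) turned to 0.786 with at least 500 genes, 0.787 with no filter, 0.711 with doublets kept and 0.484 with cells thinned.

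In monocyte/macrophage-like cells, at least 500 genes gave -0.36 for type I interferon and -1.17 for naive lymphocyte genes, and doublets kept gave -0.44 and -1.15. Those settings turned the cell cycle median of the macrophage and monocyte compartment (0.93) to -0.49 each time. Thinning to 1000 UMIs gave -0.62 for type I interferon, 0.35 for interferon gamma, -0.18 for NF-kB, 0.27 for hypoxia, -0.97 for neutrophil granule, 0.18 for cell cycle and -0.47 for B cell activation genes, turned MHC class II (-0.09) to 0.0945, the dendritic tissue remodelling median (0.33) to -0.34 and Ciita in the proliferating cluster (1.22) to -0.0850. Sign changes within counting error or with an interval that held 0 were not counted as turned: naive lymphocyte genes went from 0.40 to -0.62 in dendritic cells with means of per-cell CPM, and from 0.70 to -0.31 in the compartment without annotation-linked genes. Without the 50 most abundant genes MHC class II turned to 0.00571 and chemokines were -0.35. Means of per-cell CPM gave chemokines -0.48 and dendritic tissue remodelling -0.24. At least 100 UMIs gave neutrophil granule genes -1.001 and dendritic cell cycle genes 0.12 (from -0.44), and no minimum gave cytotoxic genes -0.10 (from 0.08) and neutrophil genes of the proliferating cluster -0.24 (from 0.48). Resolution 2 turned, in interstitial macrophages, tissue remodelling (0.34) to -0.12, dissociation stress (-0.26) to 0.20, AY036118 (-1.30) to 0.00229 and Rgs1 (-0.94) to 0.30.

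Among added alternatives, droplets counted by 3 genes without clusters gave ratios of 0.511 for T cells (from 0.115), 0.608 for B cells (from 0.216) and 0.304 for neutrophils (from 0.0964). Leaving out the highest 5% of Scrublet scores gave a compartment ratio of 1.43, a mixed ratio of 0.0720, and medians of -0.40 for type I interferon, -0.18 for NF-kB, 0.31 for hypoxia and -1.13 for naive lymphocyte genes, and turned Chil3 in dendritic cells (-4.34) to 0.40. Markers present from 10% gave 1.32 and a mixed ratio of 0.765, those from 20% a mixed ratio of 0.719, and a total without unnamed and non-immune clusters 1.36. The largest cluster alone gave -0.15 for type I interferon, 0.46 for interferon gamma, -0.13 for NF-kB, 0.44 for hypoxia, -0.71 for neutrophil granule and 0.21 for cell cycle genes, and turned Ccnb2 (1.34) to -0.56, Rsad2 (-1.07) to 0.28 and Saa3 (-3.09) to 1.18. Mmp9 had only 13 UMIs there, too few for a ratio. Leaving out annotation-linked genes gave -0.49 for chemokines and -1.88 for neutrophil granule genes, and turned chemokines to -0.13 in the compartment (0.66), -0.0898 in interstitial macrophages (0.52) and -0.54 in the proliferating cluster (0.46). Members are dropped there partly for a shift of the same sign in unrelated classes, so part of these changes can come from the choice of members.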

Other observations

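Of the tests in this part, the one on free macrophage RNA was chosen after the result was seen, in place of an earlier bound that its value neither met nor excluded.

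The 2 clusters of T cell-like cells were divided unequally. Cluster 6, led by genes of activated T cells such as Pdcd1, Ctla4 and Icos, held 74.0% of distal T cell-like cells (273 cells) and 24.3% of niche ones (9 cells). Cluster 15, led by Lef1 and Tcf7, genes of naive T cells, held 26.0% (96 cells) and 75.7% (28 cells). Only 36 of 201 niche droplets with at least 3 T cell genes lay in these clusters and 154 held macrophage RNA, so the division describes a small part of those droplets. How many of the others hold a T cell is not known. Classical monocyte-like cells, with 48 niche cells too few for the comparisons, had Cxcl9 at 4275 CPM in the niche library and 576 CPM in the distal library, where T cell-like cells had 559 and 4.53 CPM. A cluster led by Gpnmb, Trem2 and Fabp5, genes of lipid-laden macrophages, was 2.31% of niche and 0.679% of distal cells.

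Alveolar macrophage-like cells were 0.260% of the niche and 32.0% of the distal library. Loss of shallow cells was argued against by the ratio of shares among cells of at least 5000 UMIs, 0.00688 (0.00296 to 0.0136), which stayed under the bound of 0.5 set beforehand. Clusters drawn by library were argued against by a count without clusters, in cells with at least 4 alveolar macrophage markers at 1000 UMIs, where the ratio was 0.00898 (0.00360 to 0.0186). What stays open is the sort gate, which the sources used here do not give, and a true difference between niche and distal lung, neither of which was tested.

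Many niche droplets with 3 B cell genes also held at least 10 UMIs of 4 macrophage genes, 67.5% (59.7 to 74.7) against 13.9% in the distal library. Random pairs of cells in 1 droplet would give a like share for neutrophils, which was 61.1% (52.2 to 69.5). The intervals overlapped, so that prediction was met. The comparison was between cell types and did not test the size of the shares. Random pairs at the doublet rate of 0.03 assumed for Scrublet would give shares far below these, which argues against random pairing at that rate. The true rate of pairs is not known. The criterion had been written for niche B cells alone, and it was not met elsewhere: niche T cell droplets were at 76.6% (70.1 to 82.3), wholly above neutrophils, and distal B cell droplets (10.2 to 18.3) were above distal neutrophil droplets at 4.04% (2.49 to 6.17). Free macrophage RNA at the level of niche B cell-like cells would give 8.39 UMIs of these genes (3.71 to 16.3) where the median was 233, but the droplets were chosen by the same genes and that class leaves out mixed clusters, so this test decides nothing. Random pairing at a higher rate than assumed and free RNA are therefore left undecided. Cells that stay attached through sorting or a gate that favours lymphocytes bound to a labelled macrophage stay open.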
